A study of Homo sapiens with 91 samples.

How the data were processed

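The sources used here describe 91 samples, of which 48 had files that were analysed: 38 single cells and 10 averaged aliquots of 1 HEK293T clone. Groups and replicate numbers came from the labels. The other 43 samples were not analysed here. Each deposited file lists 57820 Ensembl gene identifiers with 4 columns of whole-number counts: exonic reads, exonic random barcodes, intronic reads and intronic random barcodes. Per the submitters' processing notes the authors used TopHat, HTSeq and the human build hg19, and the versions are not given in the sources used here. Whether the counting used strand is not given in the sources used here, so reads of a gene and an overlapping or antisense neighbour cannot be told apart. The counts as deposited were not normalized. Barcode counts were taken as the main measure because they count molecules before amplification. A cell held 3.23 ± 0.565 (SD) exonic reads per barcode and an aliquot 2.90 ± 0.221.

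Gene symbols were matched by identifier to GENCODE release 29 and a table of gene names, which gave a symbol to 52338 identifiers, and identifiers without a symbol held 1.59% of exonic barcodes. No coordinates are given, because the reference was on another build than the files, and it was used only for names and for which genes overlap. Pairs of libraries within a group were compared by a chi-square statistic per degree of freedom over genes, which was at least 2.16 between cells and 2.09 between aliquots, above the value near 1 of a library counted again, so no library was treated as a duplicate.

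Library factors were TMM factors of edgeR 4.0.16, and levels are CPM values of exonic barcodes. The 9992 genes with a mean of at least 10 CPM over all 48 libraries were tested. Spread was tested with limma 3.58.1 in R 4.3.3: absolute deviations of log2 CPM (prior count 1) from the group median, scaled for group size, were compared between cells and aliquots with robust and trended moderation, two-sided. A negative-binomial likelihood-ratio test of 2 group dispersions against 1 shared dispersion per gene, listed beforehand as an alternative, used Cox-Reid adjusted profile likelihoods on 60 dispersions from 0.001 to 20, written in Python 3.11.15 with numpy 2.4.6 and numba 0.67.0. Adjusted p-values are Benjamini-Hochberg values. Mean levels and genes detected were compared as values only.

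The 18 gene lists were fixed before the data were examined. Lists with at least 5 tested members (15 lists) entered camera on the deviations with a preset correlation of 0.01 and with an estimated one, and a test of coordination: the mean pairwise Spearman correlation over cells, against 10000 random lists of the same size matched in 20 bins of level, one-sided. A list score was the mean z-score of log2 CPM over tested members. A family of 8 relations between scores was tested by Pearson and Spearman coefficients with 100000 permutations, two-sided. A family of 10 relations, chosen after the data were seen and enlarged from 8 to 10 after values were known, was computed the same way. Of these 10, NEAT1 with MALAT1, AMOT with IRS4, CPAMD8 with XG and a group of 6 introns with MT-RNR1 were picked from correlation tables over the called genes, over all tested genes and over introns, and the 6 introns were grouped because they correlated. Their p-values take no account of that search. A circular phase angle was taken from the G1/S and G2/M scores.

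Named genes followed a rule fixed before the data were examined, with pseudogenes, genes without a symbol and multi-copy small RNAs left out. The rule took 12 genes with the largest ratio of cell spread to aliquot spread among those past adjusted p 0.05 in the limma test with at least 20 CPM (none with larger spread in cells passed), the 5 genes with the smallest p, the 2 members of each list with the smallest p, up to 3 genes called the other way, and the 5 highest and 5 lowest ratios of mean CPM among genes with at least 20 CPM in the higher group. This gave 47 genes, of which 3 are not reported here. The genes called by the dispersion test were named in addition, after their values were seen. XIST and genes on the Y chromosome were not named.

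Both tests were tested on counts simulated with the real means and library sizes, in which 200 of 9992 genes had extra variation between cells. These 200 were drawn from genes with a mean of at least 50 CPM, so recovery was not measured for tested genes below that level. The first simulation gave every gene the same dispersion of 0.10. In it the dispersion test recovered 0 of 100 genes with an added variation of 50% and 12 of 100 with 100%. The limma test recovered 0 of 100 at each size, although 24 and 92 had an unadjusted p under 0.05, and neither test called any of 9792 unchanged genes. A second simulation, with the real dispersions between aliquots and larger added variation, was added after the first had given this low recovery. Its dispersions were held above a floor that was higher than the lower limit of the test. The tests themselves were not altered. In the second simulation the dispersion test recovered 77 of 100 genes with an added variation of 100% and 99 of 100 with 200%, and called 4 of 9792 unchanged genes. The limma test recovered 23 and 73 of 100 and called 17 unchanged genes. The simulations differed both in the dispersions and in the added sizes, and which of these raised the recovery was not tested. The coordination test recovered a planted list of 20 genes (mean correlation 0.52) and called 0 of 5 unrelated lists.

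Alternatives were DESeq2 1.42.0 size factors, plain library totals, other filters, prior counts, centres and forms of the deviations, thinning to 128322 barcodes, regression on genes detected, exonic reads in place of barcodes, cells 1 to 10 with and without the replicate number as a block, and fits without the 2 cells with the most genes detected (cells 25 and 31) or without the 4 cells with the lowest intronic share (cells 9, 18, 36 and 38), the last 2 added after the data were seen. The smallest library held 59.1% of the median total of its group, so the planned exclusion of shallow libraries removed none. After the data were seen, a linear trend on the library number in the labels was removed as a further alternative, within each group for the limma and camera tests, and in cells only for the dispersion test, the coordination and the relations. For the dispersion test the trend of each gene was fitted on log2 CPM and entered as an offset, with no degree of freedom taken off. Bootstrap intervals drew the 38 cells with replacement, 2000 times.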

Results

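RNA was measured in libraries made by MATQ-seq, a method that reverse-transcribes total RNA at the input of 1 cell and tags each cDNA molecule with a random barcode, so that molecules and not amplified copies can be counted. The 48 libraries analysed here came from 1 clone of HEK293T, a line of transformed human embryonic kidney cells. In 38 of them the input was 1 single cell, and in 10 it was an aliquot of pooled material at the input of 1 cell, here called an averaged aliquot. The remaining 43 samples of the series, among them the libraries of MCF10A mammary epithelial cells, were not analysed here. The design asks which RNAs differ between the cells of a clone by more than the method itself scatters. The aliquots are split from pooled material, so they should carry the scatter of the method with fewer of the differences between cells. A single-cell library held a mean of 231131 exonic barcodes ± 51823 (SD, n = 38, range 128322 to 326476), and an averaged aliquot 188547 ± 41723 (SD, n = 10, range 152542 to 275215). The labels do not say whether cells and aliquots came from the same culture and day, nor whether the 10 aliquots share 1 pool, so differences between the 2 groups, in mean as in spread, can include these. P-values below speak of the cells of this clone only, and most of them rest on the variation between these libraries. Those of the coordination test come instead from random gene lists. They compare a list with other genes, which are not independent replicates, so they are descriptive. Camera with the preset correlation treats the genes of a list as nearly independent, so its p-values can be too small for lists whose genes move together.

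Protein-coding genes took 91.6% ± 1.48 (SD) of the exonic barcodes in single cells and 90.8% ± 0.754 in aliquots. Long noncoding RNAs took 2.46% ± 0.465 and 2.68% ± 0.189, and mitochondrially encoded mRNAs 1.68% ± 0.394 and 1.47% ± 0.176. Small noncoding RNAs made up a similar mean share in both groups, 0.739% in cells and 0.736% in aliquots, with an SD of 0.383 between cells and 0.120 between aliquots. A cell library showed 12934 ± 887 genes (SD, n = 38) with at least 1 exonic barcode and an aliquot 12368 ± 479 (SD, n = 10). After every library was thinned to 128322 barcodes, the numbers were 11581 ± 528 and 11512 ± 178, a difference of 68.9 genes in place of 566. Over all cells 31138 genes were seen at least once, and over all aliquots 21409, with more libraries behind the first number. No test was made on these means, because each group counts as 1 sample for a comparison of means.

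Introns took a mean of 52.8% ± 8.27 (SD, n = 38) of all barcodes in single cells and 57.6% ± 1.66 (SD, n = 10) in aliquots. Single cells ranged from 32.7% in cell 36 to 66.8% in cell 1, while aliquots stayed between 54.9% and 60.4%. Cells with a larger intronic share had a higher mean exonic score of the 13 tested members of the list of nuclear long noncoding RNAs. Pearson r and Spearman rho were both 0.594 (permutation p = 0.00011 and 0.00013, adjusted p = 0.00022 and 0.000325 over 10 relations). These relations were chosen after the data were seen, a family enlarged from 8 to 10 after values were known. Where the members of the list lie in these cells was not measured, so the score need not be of nuclear RNA alone. Cells with a larger share also had a lower score of ribosomal protein mRNAs, which are cytoplasmic messages (r = -0.609, rho = -0.54, permutation p = 9e-05 and 0.00065, adjusted p = 0.00022 and 0.000929). Without the 2 cells farthest from the median of the list score, r was 0.565 and -0.511, and with the trend on the cell number removed 0.538 and -0.526. Taken singly, also after the data were seen, 3 of the 13 RNAs (MALAT1, FTX and MIR17HG) rose with the share with both coefficients, and none did with the trend on the cell number removed (adjusted p = 0.0954 and 0.0692 for FTX, 0.00286 and 0.0692 for MIR17HG, Pearson first). MALAT1 gave r = 0.522 and rho = 0.556 (permutation p = 0.00081 and 0.00025, adjusted p = 0.00527 and 0.00325 over 13, rho = 0.507 without the 2 cells farthest from its median), but with the trend on the cell number removed r = 0.387 and rho = 0.419 (adjusted p = 0.0694 and 0.0692). NEAT1 passed with 1 coefficient only (r = 0.4, rho = 0.385, permutation p = 0.013 and 0.0175, adjusted p = 0.0424 and 0.0568, r = 0.451 without 2 cells). NORAD leaned the other way without passing (r = -0.353, rho = -0.288, permutation p = 0.0292 and 0.0808, adjusted p = 0.0758 and 0.208).

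The libraries also followed the numbers that the labels give the cells, a relation looked for after the data were seen. Of 34 measures 7 related to the number with both coefficients after adjustment. The intronic share fell along the numbers (r = -0.502, rho = -0.532, permutation p = 0.00132 and 0.00071, adjusted p = 0.00898 and 0.00483), as did the share of small noncoding RNAs (r = -0.603, rho = -0.633, permutation p = 7e-05 and 2e-05, adjusted p = 0.00119 and 0.00034), and RMRP, the RNA of RNase MRP (r = -0.686, rho = -0.707, permutation p = 1e-05 for both, adjusted p = 0.00034 for both). Without the 2 cells farthest from the median number, r was -0.403, -0.548 and -0.634. Of the 9992 genes tested, 100 rose and 67 fell along the numbers of the 38 cells at a limma adjusted p under 0.05. None did over the 10 aliquots, where fewer libraries leave less power to call genes. At an unadjusted p under 0.05 15.3% of genes passed over cells and 5.61% over aliquots. What the numbers stand for is not in the labels, so the part of the spread between cells that goes with them is not assigned to the cells. The share of small noncoding RNAs moved in steps and not along a line. It went from 1.23% in cell 5 to 0.704% in cell 6 and from 0.415% in cell 14 to 1.91% in cell 15. From cell 22 to cell 23 it went from 0.929% to 0.492%. A linear trend cannot take up such steps in full, so fits with the trend removed can still hold differences between runs of numbers.

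**Figure D1:**
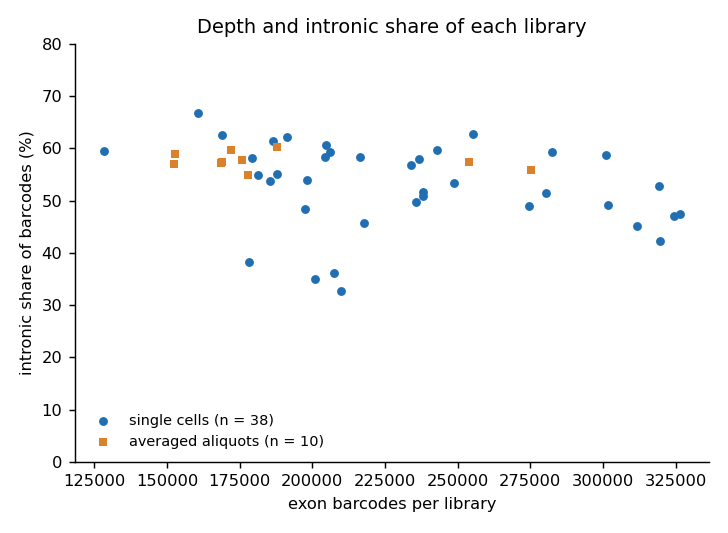
Each point is 1 library, with its number of exonic barcodes on the horizontal axis and the share of its barcodes that lay in introns, in percent, on the vertical axis, for 38 single cells (circles) and 10 averaged aliquots (squares). The aliquots lie between 54.9% and 60.4%, the cells between 32.7% and 66.8%.

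Libraries of both kinds resembled each other to a similar degree. Over the 9992 genes tested, the mean pairwise Pearson correlation of log2 CPM was 0.775 ± 0.036 (SD of 703 pairs) between cells, 0.774 ± 0.012 (SD of 45 pairs) between aliquots and 0.767 ± 0.025 (SD of 380 pairs) between a cell and an aliquot. These are correlations across genes, which are not independent replicates, so no p-value is given. They were not computed at equal depth, and cells held more barcodes than aliquots. Similar means therefore do not show that cells resemble each other as much as aliquots do. The leading component took 7.83% of the variance between cells, where even components would take 2.70%. Between aliquots it took 12.99%, where even components would take 11.1%.

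The genes that differed most between cells, relative to aliquots, were histone genes, the nuclear long noncoding RNAs NEAT1 and MALAT1, and a few single genes. NEAT1, the scaffold RNA of paraspeckles, averaged 1737 CPM in cells with a coefficient of variation of 67.9%, against 1573 CPM and 6.25% in aliquots. MALAT1, a nuclear speckle RNA, averaged 1406 CPM with a variation of 48.2% in cells and 1607 CPM with 9.47% in aliquots. JUN, an immediate-early transcription factor, varied by 96.2% around 194.6 CPM in cells and by 18.4% around 191.4 CPM in aliquots. AMOT, which encodes the junction protein angiomotin, varied by 42.4% in cells and 6.95% in aliquots around means of 1194 and 1316 CPM, and IRS4, an insulin receptor substrate abundant in these cells, by 40.5% and 11.4% around 935 and 1146 CPM.

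A negative-binomial likelihood-ratio test of 2 group dispersions against 1 shared dispersion called 21 genes with larger dispersion in cells and 1 with larger dispersion in aliquots at a Benjamini-Hochberg adjusted p under 0.05. The limma test on absolute deviations, the main test of the comparison, called 0 genes with larger spread in cells and 3 with larger spread in aliquots. In simulated counts the limma test recovered 0 of 100 genes with an added variation of 100%, all with a mean of at least 50 CPM, at 1 setting. At the other it recovered 23 of 100 and also called 17 of 9792 unchanged genes. At an unadjusted p under 0.05 the limma test passed 367 genes with larger spread in cells and 354 with larger spread in aliquots. The negative-binomial test passed 684 and 237. The balance of the limma test depended on the setting. It was 429 and 202 after thinning, 287 and 147 at a mean of at least 50 CPM, and 419 and 143 with cells 1 to 10 and the replicate block. It went the other way with, among others, squared deviations (116 and 511) and exonic reads (295 and 378). Over all tested genes the median ratio of cell spread to aliquot spread was 1.04, against 1.08 after thinning, 1.10 at a mean of at least 50 CPM and 1.00 with exonic reads. The dispersion test gave adjusted p = 5.57e-05 for NEAT1, 0.00226 for AMOT, 0.013 for MALAT1, 0.0184 for JUN and 0.029 for IRS4, whereas the limma test gave adjusted p = 0.218, 0.491, 0.491, 0.502 and 0.562 for these genes. The calls of the dispersion test rest on that test alone, which was an alternative, and the genes it called were named after their values were seen. Of the 21 genes 17 had a symbol and 4 did not.

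Single cells lay on both sides of the aliquots for these genes. For NEAT1, 16 cells lay above all 10 aliquots and 20 below all of them, with 2 inside their range. For MALAT1 the numbers were 10 above and 22 below, for AMOT 13 and 19, for IRS4 5 and 18, and for JUN 8 and 21. HMOX1, the stress-inducible heme oxygenase, had a mean of 37.6 CPM and a median of 14.5 CPM in cells, and 34 cells lay below all aliquots. It reached 563 CPM in cell 16 and 168 CPM in the next cell, while the aliquots averaged 99.2 CPM with a variation of 26.3% (adjusted p = 0.00909 in the dispersion test, 0.0437 without cell 16, and 0.696 in the limma test). Without cell 16 the mean of HMOX1 in cells was 23.4 CPM.

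Among the other genes called by the dispersion test were 2 long noncoding RNA genes. AL035425.3 averaged 244 CPM in cells, with a variation of 49.0% against 13.5% in aliquots (adjusted p = 0.0271, and 0.562 in the limma test). AL355075.4 averaged 1069 CPM in cells and 1818 CPM in aliquots, with variations of 50.7% and 12.1% (adjusted p = 0.0366, and 0.491 in the limma test). In the annotation used for names AL355075.4 overlaps RPPH1, the RNA component of ribonuclease P, and PARP2, and AL035425.2 overlaps both AL035425.3 and IRS4, so the counts of these genes are uncertain. Leaving out the cell in which each of the 21 genes was highest left 18 of them under an adjusted p of 0.05. The named genes among those lost were HIST1H2BL without cell 16 (adjusted p = 0.0551) and HIST2H2AC without cell 16 (adjusted p = 0.0568). With a linear trend on the cell number removed from the cells, an alternative chosen after the data were seen, 16 of the 21 stayed under 0.05. The named genes among those lost were AL355075.4 (adjusted p = 0.101), which fell along the numbers (r = -0.553, rho = -0.569, permutation p = 0.0004 and 0.00016, adjusted p = 0.0034 and 0.00181, r = -0.497 without the 2 cells farthest from the median number), HIST1H2BL (0.0619) and HIST2H2AC (0.0607).

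**Figure D2:**
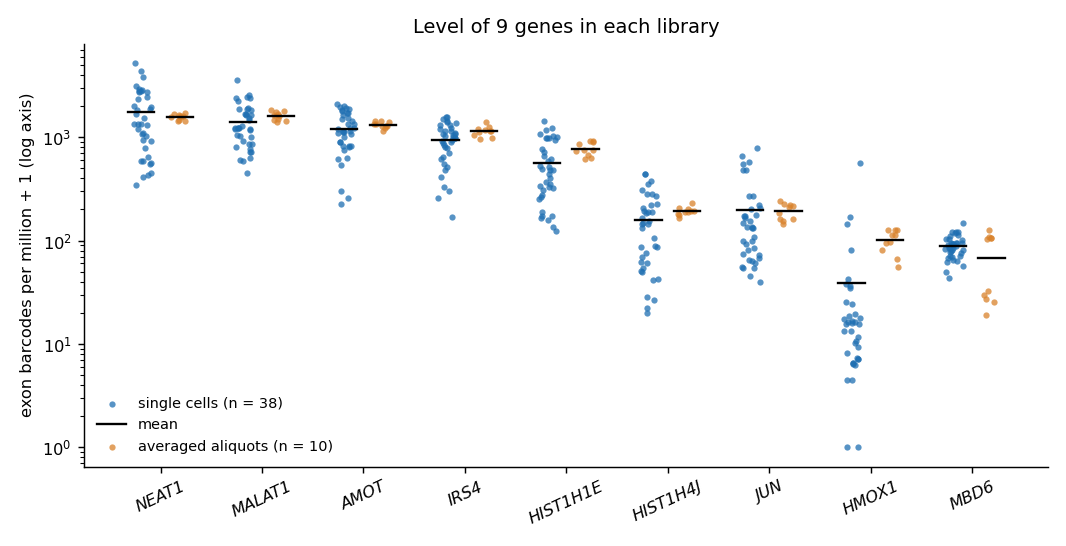
CPM of exonic barcodes, plus 1, on a log axis, for 9 genes in each of 38 single cells and 10 averaged aliquots; each point is 1 library and each black line the mean of its group. NEAT1 spans a range from 347 to 5196 CPM in cells and from 1426 to 1722 CPM in aliquots, and MBD6 shows the opposite, with 5 aliquots under 50 CPM and 5 over 100 CPM.

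Replication-dependent histone genes, which encode the histones made during DNA synthesis, gave the clearest group. All 24 tested members had larger spread in cells than in aliquots, with a median ratio of 3.31, and their median coefficient of variation was 71.3% in cells and 21.9% in aliquots. The core histone gene HIST1H4J averaged 158 CPM with a variation of 74.6% in cells, against 191.4 CPM and 9.05% in aliquots. HIST2H2AB varied by 111% and 25.7%, the linker histone gene HIST1H1C by 69.8% and 10.3%, HIST1H2AG by 75.7% and 15.7%, and HIST1H4H by 69.4% and 13.8%. For HIST1H4J and HIST1H1C, as for NEAT1 and AL035425.3, the fitted dispersion between aliquots lay at the lower limit of the test, 0.001. Such a low value over 10 aliquots can be partly a matter of chance, so the size of these contrasts is uncertain. The dispersion test called 9 members over all genes tested and 24 adjusted over the list alone, and the limma test called 0 over all genes and 24 adjusted over the list alone.

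As a set, the histone genes had excess spread in cells (camera, adjusted p = 3.7e-34 with the preset correlation, and adjusted p = 0.00906 with an estimated correlation). They also rose and fell together, with a mean pairwise Spearman correlation of 0.855 over the 38 cells and 0.317 over the 10 aliquots. None of the 10000 random lists matched on level came as high (p = 0.0001, the smallest these lists can give, adjusted p = 0.00025). The summed level of the 24 genes was 6683 CPM in cells and 10079 CPM in aliquots, with a median log2 ratio of -0.70. Histone genes share near-identical sequences, so counts of single members are uncertain. The members called by the dispersion test over all genes were HIST1H4J, HIST1H1C, HIST1H4H, HIST1H2AG, HIST1H1D, HIST1H1E, HIST2H2AB, HIST1H2BL and HIST2H2AC, with adjusted p from 0.00226 to 0.0493.

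**Figure D3:**
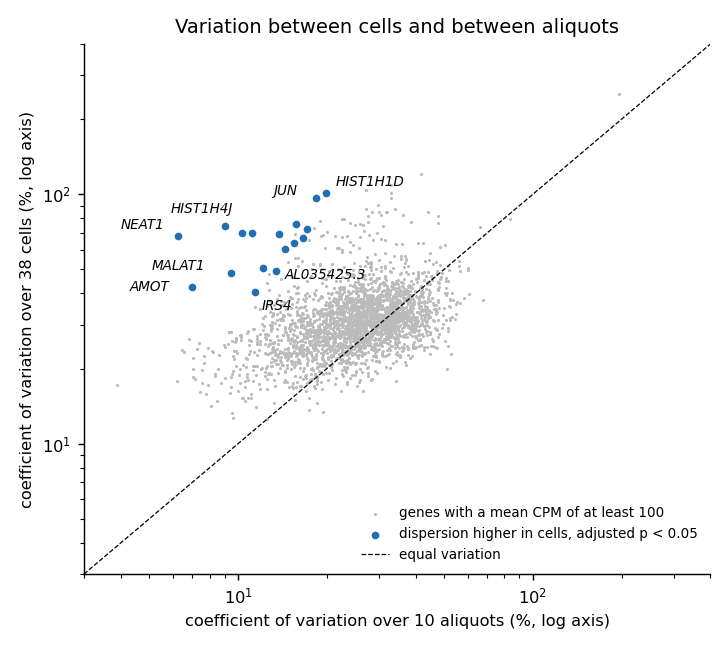
Coefficient of variation over 38 cells against that over 10 aliquots, both in percent on log axes, for genes with a mean of at least 100 CPM; the dashed line marks equal variation and blue points are genes with larger dispersion in cells. NEAT1 lies at 6.25% between aliquots and 67.9% between cells, HIST1H4J at 9.05% and 74.6%, and HIST1H1D at 19.9% and 101%.

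Genes of the G1/S and G2/M phases of the cell cycle moved together between cells. The 43 tested G1/S genes had a mean pairwise correlation of 0.367 over cells and 0.002 over aliquots, and the 52 tested G2/M genes 0.352 and 0.048 (adjusted p = 0.00025 for each, from 10000 matched random lists). MCM5, a subunit of the replicative helicase, varied by 43.0% in cells and 15.5% in aliquots, and PCNA, the sliding clamp of DNA polymerase, by 52.0% and 18.98%. The mitotic kinase PLK1 varied by 55.5% and 15.9%, and the kinetochore motor CENPE by 53.1% and 24.8%. Of the G1/S genes 37 and of the G2/M genes 43 had larger spread in cells. Neither test called a member of these lists over all genes, and adjusted over the list alone the dispersion test called 0 G1/S and 7 G2/M genes and the limma test 0 of each. The camera test gave adjusted p = 2.38e-05 for G1/S and 8.32e-07 for G2/M, and adjusted p = 0.0748 for both with an estimated correlation.

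The G1/S score fell as the G2/M score rose over the 38 cells (Pearson r = -0.612, permutation p = 6e-05, adjusted p = 0.00048; Spearman rho = -0.753, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 8e-05). Without the 2 cells farthest from the median of the G1/S score r was -0.62. It was the only 1 of the 8 relations fixed before the data were examined that passed with both coefficients. The histone score related weakly to G1/S (r = 0.201, rho = 0.203, permutation p = 0.224 and 0.221, adjusted p = 0.396 and 0.354) and to G2/M (r = -0.192, rho = -0.206, permutation p = 0.247 and 0.215, adjusted p = 0.396 and 0.354). Without the 2 cells farthest from the median of x, these were 0.235 and -0.317.

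Against the total of exonic barcodes, the G1/S score gave r = -0.062 and rho = -0.137 (permutation p = 0.713 and 0.414, adjusted p = 0.722 and 0.473). The G2/M score gave r = 0.367 and rho = 0.258 (permutation p = 0.0228 and 0.118, adjusted p = 0.0609 and 0.315). The score of mitochondrially encoded mRNAs was lower in cells of larger total (rho = -0.447, permutation p = 0.0052, adjusted p = 0.0208), but its Pearson coefficient missed the threshold after adjustment (r = -0.381, permutation p = 0.0184, adjusted p = 0.0609), and regression on the number of genes detected ended the call (rho = -0.19, adjusted p = 0.547), as did removal of the trend on the cell number (rho = -0.402, adjusted p = 0.0516). Immediate-early and heat shock scores gave r = -0.163 and rho = -0.098 (adjusted p = 0.437 and 0.557), and ribosomal protein and mitochondrial mRNA scores r = 0.06 and rho = 0.156 (adjusted p = 0.722 and 0.465), with permutation p = 0.328, 0.557, 0.722 and 0.349 in that order. Without the 2 cells farthest from the median of x, r for these 5 relations was -0.159, 0.283, -0.244, -0.07 and 0.042 in the order given. The labels name no batch of cells within which the relations could be repeated, but with the trend on the cell number removed G1/S and G2/M still gave rho = -0.749.

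**Figure D4:**
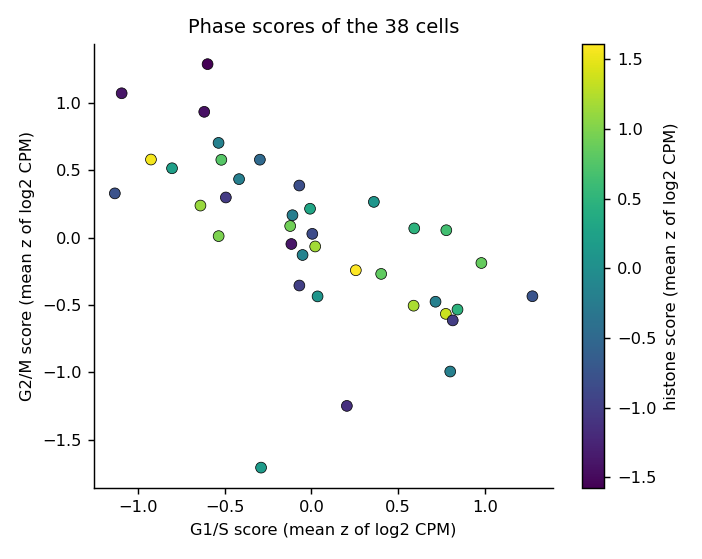
Each point is 1 of the 38 cells, placed by its G1/S score and its G2/M score (mean z-score of log2 CPM over the tested members of each list) and coloured by its histone score. The G1/S score falls as the G2/M score rises (r = -0.612).

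Mitochondrially encoded mRNAs and cytosolic ribosomal protein mRNAs were coordinated as well. The 13 mitochondrial mRNAs, which encode subunits of the respiratory chain, had a mean pairwise correlation of 0.764 over cells and 0.414 over aliquots, and the 74 ribosomal protein genes 0.384 and 0.085 (adjusted p = 0.00025 for each). All 13 mitochondrial mRNAs and 70 of the ribosomal protein genes had larger spread in cells. MT-ATP6 varied by 31.9% in cells and 12.1% in aliquots, of which aliquot 2 stood apart at 429 CPM, MT-ND4 by 27.5% and 12.4%, RPL30 by 26.2% and 6.81%, and RPS6 by 17.2% and 3.88%. Neither test called a member over all genes, and the dispersion test called 18 ribosomal protein genes and 0 mitochondrial mRNAs adjusted over the list alone (limma test, 0 of each). In the camera test adjusted p was 2.63e-06 for mitochondrial mRNAs and 1.55e-10 for ribosomal proteins, and with an estimated correlation adjusted p = 0.0963 and 0.0748.

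Heat shock genes, which encode chaperones, varied together to a smaller degree, with a mean pairwise correlation of 0.221 over cells and 0.057 over aliquots (adjusted p = 0.00025). Of 12 tested members 11 had larger spread in cells, among them HSPA8 (23.95% in cells and 7.25% in aliquots) and HSPA1B (67.2% and 22.4%), and their excess spread passed with both forms of the camera test (adjusted p = 2.38e-05, and adjusted p = 0.0259 with an estimated correlation). Adjusted over the list alone, the dispersion test called 6 of them and the limma test 0. Immediate-early genes did not move together (mean pairwise correlation -0.006 in cells, adjusted p = 0.573), although JUN and MYC varied by 96.2% and 68.2% between cells and by 18.4% and 19.2% between aliquots. MYC missed the threshold of the dispersion test (adjusted p = 0.0504, and 0.562 in the limma test). The dispersion test called 1 of 8 immediate-early genes over all genes and 4 adjusted over the list alone, the limma test 0 and 2, and camera gave adjusted p = 0.0148 and adjusted p = 0.0705 with an estimated correlation.

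Genes of the unfolded protein and integrated stress response, glycolysis and cholesterol synthesis showed weak coordination, with mean pairwise correlations of 0.120, 0.132 and 0.077 over cells and 0.001, 0.071 and 0.024 over aliquots (adjusted p = 0.00107, 0.0015 and 0.00112). Their examples were HSP90B1 (22.1% in cells and 7.01% in aliquots) and ATF4 (33.7% and 12.8%), ENO1 (20.0% and 7.02%) and PKM (18.6% and 8.36%), and FDFT1 (35.2% and 11.4%). None of these 5 genes passed either test. Camera gave adjusted p = 0.0378, 0.0331 and 0.0331, and adjusted p = 0.0963, 0.141 and 0.108 with an estimated correlation, and with the trend on the library number removed adjusted p = 0.0546, 0.0691 and 0.0672 with the preset one. Adjusted over the list alone the dispersion test called 5, 3 and 1 members and the limma test 0 of each list.

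The nuclear long noncoding RNAs as a list were not coordinated beyond random lists (mean pairwise correlation 0.037 in cells, adjusted p = 0.0849), and NEAT1 and MALAT1 were the 2 members that the dispersion test called, over all genes and adjusted over the list alone. The limma test called 0 over all genes and 2 adjusted over the list alone, and camera gave adjusted p = 0.0266, and adjusted p = 0.0748 with an estimated correlation. Over cells NEAT1 and MALAT1 had r = 0.595 and rho = 0.618 (permutation p = 0.00014 and 4e-05, adjusted p = 0.000233 and 0.000133 over 10 relations, r = 0.567 without the 2 cells farthest from the median of NEAT1). This pair was picked from a table of correlations between the called genes, so these p-values understate the search and are no test of the relation. Small nucleolar RNA host genes had a correlation of 0.123 over cells and -0.015 over aliquots (adjusted p = 0.00225) and no excess spread (camera adjusted p = 0.275), with SNHG8 at 47.1% and 23.7% and SNHG7 at 53.1% and 54.0%, and 0 members called by either test adjusted over the list alone. Of the abundant small noncoding RNAs 3 members were tested, and RMRP varied by 52.4% in cells and 20.8% in aliquots, while TERC, the telomerase RNA, varied by 54.6% and 24.7%. Adjusted over the list alone the dispersion test called 3 of them and the limma test 1. Their mean pairwise correlation was 0.384 over cells, 0.235 with the trend on the cell number removed, and 0.806 over aliquots, without a test for so few members. TERC, like RMRP, fell along the cell numbers (r = -0.435, rho = -0.448, permutation p = 0.0067 and 0.00546, adjusted p = 0.0285 and 0.0265).

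The p53 targets were coordinated at a low level (0.094 over cells, 0.012 over aliquots, adjusted p = 0.0045) with no excess spread (camera adjusted p = 0.798), and SESN1 varied by 65.9% in cells and 79.6% in aliquots and XPC by 60.3% and 45.3%. Kidney development and neural-type genes had a correlation of 0.044 in cells (adjusted p = 0.162), with NEFM, a neurofilament gene, at 94.1% in cells and 39.7% in aliquots. Camera gave adjusted p = 0.0318 for this list and adjusted p = 0.0748 with an estimated correlation. Housekeeping reference genes had a correlation of 0.053 in cells (adjusted p = 0.105, but 0.0134 after regression on genes detected and 0.0474 with the trend on the cell number removed), with RPLP0 at 26.5% in cells and 9.81% in aliquots (camera adjusted p = 0.0187, and adjusted p = 0.0748 with an estimated correlation). Adjusted over the list alone, the dispersion test called 0 p53 targets, 1 kidney or neural-type gene and 4 housekeeping genes, and the limma test none of these. None of the 16 markers of basal mammary epithelium reached a mean of 10 CPM. Of the blood and stroma markers 1 did, COL1A1 with 14.9 CPM in cells and 10.2 CPM in aliquots.

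**Figure D5:**
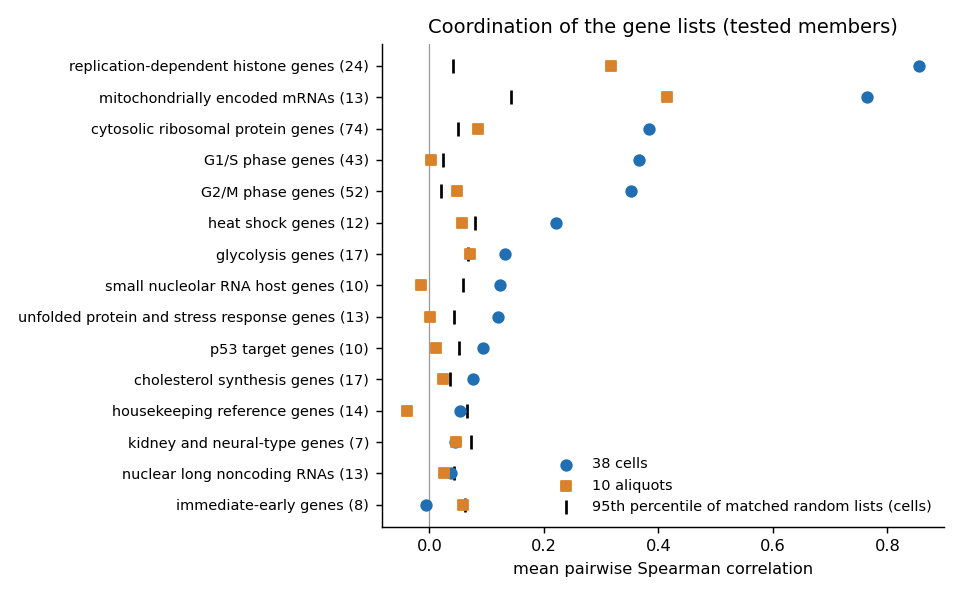
Mean pairwise Spearman correlation of the tested members of each list (number in brackets) over 38 cells (circles) and 10 aliquots (squares), with the 95th percentile of 10000 random lists of equal size and level in cells (ticks). Histone genes (0.855) and mitochondrial mRNAs (0.764) lie farthest to the right in cells.

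MBD6, PCMTD2 and FUCA1 showed the reverse, with larger spread between aliquots than between cells. MBD6, which encodes a methyl-CpG-binding domain protein, varied by 66.0% around 67.5 CPM in aliquots and by 25.4% around 87.3 CPM in cells (limma adjusted p = 5.83e-05, dispersion test adjusted p = 0.0339). It lay between 17.9 and 31.5 CPM in 5 aliquots and between 102.5 and 125.7 CPM in the other 5. PCMTD2 varied by 79.5% in aliquots and 34.2% in cells (limma adjusted p = 0.0301), and FUCA1, the lysosomal fucosidase gene, by 91.9% and 46.5% (limma adjusted p = 0.0475), and the dispersion test gave adjusted p = 0.0577 and 0.247 for these genes. CHMP1A, with the next smallest p, varied by 63.1% in aliquots and 36.3% in cells (limma adjusted p = 0.113).

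Mean levels of cells and aliquots were close for most genes. Among 8541 genes with at least 20 CPM in the higher group, 49 had means at least 2-fold higher in cells and 49 at least 2-fold lower, with a correlation of 0.965 across genes. These are values without a test, since each group counts as 1 sample. The vitamin D receptor gene VDR averaged 29.4 ± 20.1 CPM (SD) in cells against 8.36 CPM in aliquots, UPP1, which encodes uridine phosphorylase, 22.01 ± 15.5 against 6.56 CPM (29.8 CPM in aliquot 5, and a mean of 3.98 CPM in the others), MAP4K2 21.7 ± 14.5 against 6.49 CPM (41.8 CPM in aliquot 3, at most 13.1 CPM and a mean of 2.57 CPM in the others) and FIG4, a phosphoinositide phosphatase gene, 25.3 ± 15.9 against 7.97 CPM. TENM1, a teneurin gene, averaged 28.996 CPM in cells and 5.82 CPM in aliquots, but its median in cells was 4.89 CPM and its mean 17.7 CPM without cell 11, which reached 447 CPM.

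Genes with the lowest ratio were CPAMD8, PHKG1, HMOX1, ZNF680 and XG. CPAMD8 averaged 130 ± 103 CPM (SD, n = 38) in cells and 484.5 CPM in aliquots, where it ranged from 102 to 1341 CPM. XG, a blood group antigen gene, averaged 119 ± 87.5 CPM in cells and 299 CPM in aliquots, where it ranged from 84.3 to 739 CPM. ZNF680 averaged 13.3 CPM in cells and 34.1 CPM in aliquots (128.9 CPM in aliquot 7 and at most 39.9 CPM in the others), and PHKG1, a phosphorylase kinase subunit gene, 7.44 and 20.2 CPM. For HMOX1 the mean of 37.6 CPM in cells compared with 99.2 CPM in aliquots, all of which lay between 53.9 and 126.5 CPM.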

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

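The tests of library depth for the intronic share, drift along the cell numbers, nuclear RNA yield, cell cycle phase and shared reads, the splits for the dispersion test, the group of 6 introns and the bounds for single introns, were chosen only after the results were seen. In 10 aliquots, a lowest or highest value whose gap to its neighbour exceeded Dixon's 95% critical value was found for 4 of 60 measures, where chance gives about 1 in 20. Aliquot 2 had the lowest share of mitochondrial mRNA, 1.01% against 1.44% in the next, and the lowest MT-ATP6, 429 CPM against 609 CPM in the next. Aliquot 3 had the highest MAP4K2 (41.8 CPM, next 13.1 CPM). Aliquot 7 had the highest ZNF680 (128.9 CPM, next 39.9 CPM).

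The intronic share of barcodes differed far more between cells (SD 8.27, n = 38) than between aliquots (SD 1.66, n = 10). With the trend on library total removed, the SD over cells was still 4.88 times that over aliquots, and with the linear trend on the cell number removed 4.36 times, which argues against depth or a linear drift as the whole cause. Steps between runs of cell numbers were not tested, and a linear fit cannot exclude them. Genomic DNA would raise the share of intronic barcodes in genes without any exonic barcode (6753 genes), but that share fell as the intronic share rose (rho = -0.56, permutation p = 0.0003, and rho = -0.293, permutation p = 0.0761, with the trend on the cell number removed), which argues against it, less firmly within that trend. A varying yield of nuclear RNA, technical (lysis) or biological (nuclear content of the cell), may lie behind the relation to nuclear long noncoding RNAs (rho = 0.594), a hypothesis only, since the members of that list had a mean pairwise correlation of just 0.037 over cells (adjusted p = 0.0849) and 3 of its 13 members rose with the share singly, none with both coefficients once the trend on the cell number was removed. The phase angle took up a part of 0.149 of the variance (circular-linear R2, permutation p = 0.0593, bootstrap 95% interval 0.0309 to 0.437), which leaves cell cycle phase open.

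Histone genes rose and fell together between cells, in 24 tested members. Reads shared between near-identical copies are argued against by pairs of a linker and a core histone gene, whose sequences differ, with a mean rho of 0.858 over 63 pairs (0.698 to 0.95). Depth is argued against by a mean correlation of 0.861 after regression on the number of genes detected, and a linear drift along the cell numbers by 0.851 after its removal. Cell cycle phase, the biological explanation to be looked for in dividing cells, remained open, since the phase angle took up a part of 0.0701 of the variance (R2, permutation p = 0.278, bootstrap 95% interval 0.00484 to 0.351). The 4 identifiers without a symbol among the 21 calls of the dispersion test followed the histone score (rho from 0.854 to 0.977). Some histone identifiers of the annotation used by the authors got no symbol here and so did not enter the list. These 4 may therefore be histone genes themselves and not separate genes that move with them.

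Intronic barcodes, which the comparisons above did not use for single genes, called 10 genes with larger dispersion in cells and XPA with larger dispersion in aliquots (33.3% in cells, 82.6% in aliquots, adjusted p = 0.0429). Among the 10 were HFM1 (51.6% in cells, 9.57% in aliquots), ANKRD30BL (52.3% and 7.99%), PDE3A (64.6% and 9.48%), DLG2 (71.8% and 9.19%) and SEC14L1 (56.9% and 10.7%). AL035425.2, which overlaps AL035425.3 and IRS4, had the smallest p (dispersion test adjusted p = 0.00662). Mean intronic levels in cells were 6963 CPM for HFM1, 6310 CPM for ANKRD30BL and 4492 CPM for PDE3A. Whether these introns hold repeated sequence, or sequence like that of an abundant RNA, was not tested. The mean pairwise rho of the 10 introns, 0.293, lay between the 2 bounds set beforehand. That planned test thus left a source shared by all 10 undecided. A check chosen after the values were seen cannot decide it either, since its bound was set with the pairwise values known. In that check AC139769.2 and LPAR3 had a bootstrap 95% upper bound under 0.5 for rho with each of the other 9 (highest 0.47 and 0.477). LPAR3 averaged 74.0 intronic CPM in cells, a low level at which counting scatter can lower a correlation. The 15 pairs among ANKRD30BL, DLG2, HFM1, PDE3A, SEC14L1 and AC024563.1 lay at 0.688 to 0.933 and the other 30 pairs at -0.352 to 0.292, so a source shared by these 6, which were grouped by their correlation, was left untested. The mean score of the 10 introns had a rho of -0.227 with the intronic share, while the Pearson r was -0.517 (-0.342 without the 2 cells farthest from the median of the score), and with the trend on the cell number removed rho was -0.416 and r -0.61, which leaves that explanation open, and no biological explanation was tested.

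The 48 libraries were split 100 times into 38 and 10, the real split included. Only the real split gave as many as 21 genes with larger dispersion in cells, and the highest other gave 2. That share of 1 in 100 is the smallest these splits can give, so it argues against a random grouping without excluding it. The splits cannot tell differences between cells from a difference in culture, day or pool between the groups. Toward the group of 10 the dispersion test gave 1 gene in the real split and up to 3 in random ones. A count of 1 there is thus no more than random splits can give. For the limma test 2 splits gave at least 3 calls in either direction, the real one and 1 other with 3, a share of splits under 0.05. All limma calls in random splits were of larger spread in the group of 10. A lean of its calls toward the smaller group is therefore not particular to the aliquots. For the lists with excess spread in cells 1 split, the real one, gave 13, and the highest other gave 5. Counted in either direction the highest other gave 6, and many random splits called at least 1 list. Adjusted p-values of camera for single lists, with the preset correlation, are therefore too small to be taken at face value.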

How the results depend on the processing

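The fits that leave out cells, the removal of the trend on the library number and the alternatives of the dispersion test were chosen after the data were seen. The count of 0 genes with larger spread in cells stayed at 0 in the limma fits, except for 1 gene with deviations from the group mean and 2 with no filter on low counts, and the negative-binomial test gave 21. The 3 genes with larger spread in aliquots became 5 with deviations from the group mean or no filter, and 1 with a mean of at least 50 CPM, a prior count of 5, squared deviations, thinning, the negative-binomial test or without the 4 cells of lowest intronic share. With cells 1 to 10 and the replicate number as a block they became 0 and those in cells stayed at 0, as without the block. Cells and aliquots share only the number: same-numbered libraries had a mean correlation of deviations of 0.0006 (-0.0434 to 0.046), and 1 of 10 cells correlated best with its own number. The 21 calls of the dispersion test became 6 with cells 1 to 10 (fewer cells), 8 with no filter (32310 genes tested), 35 at a mean of at least 50 CPM (5170 genes tested) and 47 with exonic reads, where 18 of the 21 were shared. Its 1 gene in aliquots became 0 with cells 1 to 10 or no filter, 3 with exonic reads and 2 without the 2 cells with the most genes or with the trend on the number removed in cells, where 16 of the 21 stayed. The 13 lists with excess spread became 2 with an estimated correlation (histone and heat shock genes), 12 without the 4 cells of lowest intronic share and 10 with the trend on the number removed. Relations passing with both coefficients were 2 in place of 1 without the 2 cells with the most genes, the added relation being that of mitochondrial mRNA with the total, whose rho was -0.19 after regression on genes detected. The cause was not tested except where stated. The difference in genes detected was 489 at 3 barcodes and 68.9 after thinning. CPM of at least 1 equals 1 barcode at these depths, so that alternative changed nothing. Other counts stayed within 1.5 times their value: coordinated lists 11 to 12 (housekeeping genes added after regression on genes detected or with the trend on the number removed) and genes at least 2-fold apart 94 to 99. Depth limits the test to genes of at least 10 CPM, a few barcodes per library.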

Other observations

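The relations here were chosen only after the data were seen: each pair was picked because it stood out in a scan of correlation tables over the called genes, all tested genes or introns. The p-values and the adjustment over 10 relations take no account of that search, so they describe these pairs and do not test them. CPAMD8 and XG, the genes with means 3.74-fold and 2.52-fold higher in aliquots, were correlated. Over the 10 aliquots their log2 CPM gave r = 0.946 and rho = 0.952 (permutation p = 5e-05 for both, r = 0.895 without the 2 aliquots farthest from the median of CPAMD8). Over the 38 cells they gave r = 0.793 and rho = 0.747 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give, adjusted p = 0.0001 and 5e-05, r = 0.673 without 2 cells). The relation between pool-and-split aliquots, which the labels do not assign to 1 pool or several, was left without a tested explanation.

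AMOT and IRS4, a pair of genes on the X chromosome in the annotation used for names, were also correlated over cells (r = 0.681, rho = 0.55, permutation p = 2e-05 and 0.0006, adjusted p = 0.0001 and 0.000929). Without the 2 cells farthest from the median of AMOT, r was 0.477. The mean score of 6 introns, grouped because they correlated with each other, was related to the mitochondrial ribosomal RNA MT-RNR1 (r = 0.616, rho = 0.715, permutation p = 7e-05 and 1e-05, adjusted p = 0.00022 and 5e-05, r = 0.644 without 2 cells). Whether those introns hold sequence like that of MT-RNR1 was not tested.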
